A study of Synechocystis sp. PCC 6803 with 62 samples.

How the data were processed

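Total RNA from 62 samples of Synechocystis was, per the labels, labelled directly with Cy3 without cDNA synthesis and hybridised to single-channel Agilent arrays, 1 array for each light regime and time point. Each deposited array file holds raw spot intensity values from Feature Extraction 10.7.3.1, per the file headers: a background-subtracted and detrended processed signal, the mean and local background intensity, and flags (0 or 1) for saturation, outlier spots and spots well above background. Nothing was normalised between arrays in these files. The deposited series matrix holds the authors' own log2 values, whose normalization is not stated. Its log2 values correlated at 0.9809 to 0.9998 with the log2 mean signal of the array of the same name, and each of the 62 columns matched its own array best. With the log2 processed signal the correlation was lower, at 0.8419 to 0.9615, so the matrix lies closer to the signal before background subtraction. The medians per array lay between 10.995 and 11.505. How its background was treated is not stated. The matrix was used as an alternative only.

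Each array holds 40886 spots besides 1417 control spots, which were left out. Over all 62 arrays together 1472 spots marked as outliers were left out, and 0 spots were saturated. The log2 processed signal of the 2 spots of a probe was averaged, probes well above background on fewer than 6 of the 62 arrays were dropped, which kept 18045 of 20363 probes, and probes were averaged per feature, which gave 8210 of 8850 features. By the names in the files these are 3323 coding, 1612 antisense (suffix as), 528 NC, 1780 internal (int), 680 5'UTR, 285 other, 1 rRNA and 1 tRNA features. The files do not explain the suffixes. Features appear under the locus tags that the files use. The gene table at hand (assembly ASM28445v1) holds none of these tags, so 0 matched, and gene symbols come only from 20 gene lists written by locus tag before the data were examined. Features outside the lists are given by identifier, at most 2 higher and 2 lower per comparison.

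Arrays were scaled by subtracting, on the log2 scale, the 75th percentile over the 5301 spots well above background on all 62 arrays. This set was used because most probes were not detected on most dark arrays. Stable RNA could not serve as a reference, since its spots lay near the top of the scanner range. No reference for the total amount of mRNA per cell exists in the data, so a shift common to all features cannot be told from scaling, and list medians are given relative to the median of all features. The number of arrays limits the precision. Spots well above background per array ranged from 7633 to 36112.

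Groups follow the labels for regime, day and circadian time. Comparisons were fitted with limma 3.58.1 (lmFit and eBayes) in R 4.3.3 with data.table (version 1.17.8) and statmod 1.5.0, with Benjamini-Hochberg adjusted p under 0.05 as the threshold. Circadian time entered as a factor where 2 regimes were compared at matched time. The dawn and dusk comparisons used 10 within-regime differences in 1 fit with a shared spread: 3 lights-on dawns, 3 dawns without a change of light, 2 lights-off dusks and 2 dusks without a change of light. Rhythms were tested with the F-test of a cosine and sine term of 24 h. Day-night differences were compared between regimes in 1 fit of 56 arrays. Each gene list was tested with camera at its preset correlation of 0.01 and with an estimated correlation, and with fry, adjusted over the 20 lists of a comparison. Camera called 92 list and comparison pairs at the preset correlation and 0 with the estimated one. Fisher's exact test compared shares of rhythmic features.

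The comparisons, lists, the rule for named genes and most alternatives were fixed before the data were examined. The rule names all clock and sigma factor genes, up to 4 called and 2 uncalled members of each other list with the largest differences, and the features with the largest rise and fall; the text prints part of these. A fold is given as a lower bound where a feature was well above background on none of the arrays of 1 group, and a feature seen on part of the arrays is given as a difference. Alternatives were normexp background correction (offset 50) with the 75th percentile, quantile normalization, no scaling, the authors' matrix, no filter on dim probes, slide as a block, a linear trend for rhythms, no term for circadian time, 24 h and 12 h cosines together, subtraction of the difference before the transfer and leaving out arrays. Chosen after seeing the data were the 75th percentile over all probes, scan day as a block, a filter on brightness, leaving out the LDLDL night arrays of slide 3 or 6, leaving out LDLLL arrays in turn, leaving out the LDLLL array 30 min after lights-on, and all alternatives for the share of rhythmic noncoding features. The arrays lie on 16 slides of up to 4 arrays scanned on 10 days, and each slide holds 1 regime only.

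The fits were tested on simulated data, normal noise with the residual spread of each feature, in which 67 of 8210 features were changed by log2 0.5, 67 by log2 1 and 66 by log2 2. The simulated data have no background floor, so recovery may be overstated for features near background, above all on the dark arrays. Far fewer features were changed than were called at lights-on (6192), so the adjusted threshold was stricter there and recovery may be understated. The spread came from a fit over all groups, not from each comparison, so the rates are only a rough guide. For day against night in LDLDL 32.8%, 86.6% and 100% were recovered, with 10 false calls. At lights-on dawn 3% of the changes of log2 1 and 80.3% of those of log2 2 were recovered, at lights-off dusk 1.5% and 16.7%. For the LDLLL subjective night 52.2% of the changes of log2 1 were recovered, for the LDDDD subjective day 79.1% and for the prolonged night 56.7%. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9, with numpy 2.4.6 and pandas 2.3.3.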

Results

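Transcript levels were measured in the cyanobacterium Synechocystis under 3 light regimes, with 1 single-channel array for each regime and time point and 62 arrays in all. The LDLDL samples come from a cycle of 12 h light and 12 h darkness, with 14 day and 12 night arrays. The LDLLL samples come from a light-dark cycle followed by unbroken light, with 5 arrays of lit day hours and 2 night arrays before the light stayed on. They continue with 6 arrays of the subjective night (the hours that would have been dark) and 3 of the following lit morning. The LDDDD samples come from a light-dark cycle followed by unbroken darkness, with 2 day and 2 night arrays before the transfer. After it came 10 arrays of the subjective day (the hours that would have been lit) and 6 of the prolonged night. Circadian time (CT) counts hours from dawn.

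Signal over background differed with the light. The median share of the 40886 spots well above background was 67.6% on the LDLDL day arrays, 42.9% on the LDLDL night arrays, 78.8% in the LDLLL subjective night, 31.7% in the LDDDD subjective day and 34.1% in the LDDDD prolonged night. Single arrays ranged from 7633 to 36112 such spots. Each array counts as 1 sample and there are no biological replicates of a time point, so p-values measure a spread between arrays. For day against night it is the spread between time points, and for rhythms the spread around the curve. Between regimes at matched CT it is the spread of arrays of the same CT and of the regime difference over CT. At dawn and dusk it is the spread of the differences of a kind, pooled over regimes. Gene values below are log2 differences ± standard error from limma with p adjusted over 8210 features. List values are medians relative to the median of all features in the same comparison. The number of arrays limits the precision.

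The day and night arrays of LDLDL show which transcripts follow the light-dark cycle. Photosynthesis genes stood higher by day: all 12 photosystem I genes, all 13 phycobilisome genes, all 9 ATP synthase genes and 22 of the 23 measured photosystem II genes rose, with list medians of 4.52, 3.51, 3.18 and 2.92. psaC (ssl0563), the iron-sulfur subunit of photosystem I, was higher by 6.35 ± 0.44 (adjusted p = 9.88e-13) and apcA (slr2067), an allophycocyanin of the light-harvesting antenna, by 5.92 ± 0.38 (adjusted p = 2.93e-13). atpH (ssl2615) of the ATP synthase rose by 5.88 ± 0.36 (adjusted p = 1.26e-13) and psbO (sll0427) of the water-splitting complex by 5.27 ± 0.30 (adjusted p = 3.53e-14). The small heat shock gene hspA (sll1514) moved the other way, with a difference of -5.62 ± 0.55 (adjusted p = 5.83e-10). All 35 ribosomal protein genes rose (median 2.28), rps9 (sll1822) by 3.75 ± 0.23 (adjusted p = 1.27e-13) and rpl13 (sll1821) by 3.73 ± 0.21 (adjusted p = 3.5e-14). All 13 genes of CO2 fixation and the carboxysome rose (2.72), rbcX (slr0011) by 5.08 ± 0.32 (adjusted p = 1.89e-13) and rbcS (slr0012), the small subunit of Rubisco, by 4.50 ± 0.34 (adjusted p = 4.91e-12).

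Further lists rose by day as well. All 5 RNA polymerase core genes (2.34), all 17 genes of NDH-1 and the terminal oxidases (1.99), 13 of 16 genes of chlorophyll and bilin synthesis, where 1 fell (1.72), and 12 of 13 genes of type IV pili (1.15) were higher. The set test camera called these 4 lists and the 6 above at its preset correlation, with adjusted p from 2.72e-08 for the ribosomal proteins to 0.025 for RNA polymerase. With an estimated correlation no call held: adjusted p = 0.503 for chlorophyll and bilin synthesis and adjusted p = 0.353 for the other 9.

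Camera called none of the other 10 lists. In nitrogen assimilation 12 of 18 genes rose and 2 fell (0.88), among them the ammonium transporter gene amt1 (sll0108) at 3.97 ± 0.38 (adjusted p = 3.54e-10) and the glutamine synthetase gene glnA (slr1756) at 3.56 ± 0.39 (adjusted p = 4.99e-09). Inducible inorganic carbon uptake had 6 of 8 genes higher (1.29), including the bicarbonate transporter gene sbtA (slr1512) (adjusted p = 0.00373) and ndhD3 (sll1733) of the inducible CO2 uptake complex at 3.23 ± 0.72 (adjusted p = 0.000285). The bidirectional hydrogenase had 5 of 5 higher (0.72), glycogen synthesis 3 of 4 (0.56), glycogen breakdown and the oxidative pentose phosphate pathway 9 of 11 (0.33). Cell division and replication had 4 of 6 higher and 1 lower (0.33) and the high-light-inducible proteins 1 of 4 higher (0.13). Of 11 chaperone and protease genes 4 rose and 3 fell, with a median of 0.21 although camera pointed down, and dnaK2 (sll0170) stood at -1.33 ± 0.20 (adjusted p = 1.13e-06). Adjusted over the list alone, the counts were the same except for 7 inorganic carbon uptake genes, 13 nitrogen genes that rose and 1 clock gene.

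Sigma factors, which direct RNA polymerase to promoters, split, with 3 of 9 higher and 2 lower (list median -0.40). The principal sigma factor gene sigA (slr0653) rose by 2.46 ± 0.37 (adjusted p = 1.41e-06) and sigE (sll1689) by 1.92 ± 0.40 (adjusted p = 0.000132), while sigH (sll0856) stood at -1.45 ± 0.19 (adjusted p = 1.2e-07) and sigI (sll0687) at -0.96 ± 0.19 (adjusted p = 6.2e-05), a call that ended without scaling. The remaining call, sigF (slr1564) at 0.57 ± 0.17 (adjusted p = 0.00404), turned negative under quantile normalization and under the 75th percentile over all probes. Of 11 clock and output genes 3 rose (-0.11), the response regulator gene rpaB (slr0947) by 1.49 ± 0.27 (adjusted p = 1.94e-05). The others were kaiB2 (sll1596), higher by at least 1.05-fold but without a rise after normexp correction, and kaiB3 (sll0486) by 0.68 ± 0.25 (adjusted p = 0.0157), which turned negative under the 75th percentile over all probes. Both of these calls also ended under quantile normalization, with slide as a block and without the arrays 30 min after dawn or the night arrays of slide 3. The clock gene kaiA (slr0756) had 0.75 ± 0.44 (adjusted p = 0.13) and was called without scaling. Outside the lists, ssl3803 at 5.83 ± 0.37 and the noncoding NC-349 at 5.66 ± 0.43 were among the largest rises. slr0271 at -3.11 ± 0.38 and NC-792 at -2.62 ± 0.31 were among the largest falls.

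Over all features 5579 of 8210 differed between the 14 day and 12 night arrays, 4207 higher and 1372 lower by day, with a median over all features of 0.53. Of the 4207 features 87 were well above background on only a minority of the day arrays. Of the 1372 features 190 were so on only a minority of the night arrays. The share higher, 75.4%, ran from 39.8% under the 75th percentile over all probes to 98.4% without scaling. Within the 4 slides that hold LDLDL arrays of both phases, with 1 night array each, the photosystem I median relative to all features ran from 1.94 to 5.23 and that of the ribosomal proteins from 1.87 to 3.18. With slide as a block 5001 features were called and the medians of photosystem I and the ribosomal proteins were 3.92 and 2.24.

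A cosine of 24 h fitted to the 26 LDLDL arrays places each transcript in the day. The mean peaks of the clock and the high-light-inducible list lay near dawn, at 1.4 h for both over the 7 of 11 and 4 of 4 rhythmic members. Of these members rpaB with a peak at 6.44 h and hliD (ssr1789) with a peak at 6.54 h came near midday. Those of cell division and replication at 2.8 h (6 of 6, with dnaA (sll0848) alone among them at night, at 17.57 h, a call that ended without scaling, with the authors' matrix, with slide as a block and without the 4 night arrays of slide 6) and glycogen synthesis at 3.5 h (4 of 4) lay in the early day, while the 7 rhythmic chaperone and protease genes had scattered peaks (mean 2.1 h, vector strength 0.29). Further mean peaks were those of chlorophyll and bilin synthesis at 4.6 h (16 of 16, with acsF2 (sll1874) alone among them at night, at 17.74 h, a call that ended without scaling), ribosomal proteins at 5.1 h (35 of 35) and ATP synthase at 5.4 h (9 of 9). Photosystem II lay at 6.3 h (22 of 23), phycobilisome at 6.5 h (13 of 13) and photosystem I at 7 h (12 of 12). Glycogen breakdown at 7.9 h (9 of 11) and inducible inorganic carbon uptake at 9.1 h (8 of 8) came late in the day. Peak-to-trough log2 amplitudes were 2.27 with a peak at 0.89 h (adjusted p = 0.000765) for kaiA, 3.42 with a peak at 7.62 h (adjusted p = 6.36e-06) for sigE, 8.70 with a peak at 6.87 h (adjusted p = 2.76e-07) for psaC and 7.35 with a peak at 9.15 h (adjusted p = 6.77e-09) for sbtA. Amplitudes of genes that peaked at night were 8.04 with a peak at 19.12 h (adjusted p = 4.13e-07) for hspA and 1.97 with a peak at 18.18 h (adjusted p = 5.53e-05) for sigH. In all 5562 features (67.7%) had a rhythm, with a median amplitude of 1.67. Of these 2381 peaked from 0 to 6 h, 1714 from 6 to 12 h, 327 from 12 to 18 h and 1140 from 18 to 24 h. Peaks were not counted under the other scalings, which widely moved the share of features higher by day. The split between day and night peaks may therefore depend on the scaling.

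**Figure D1:**
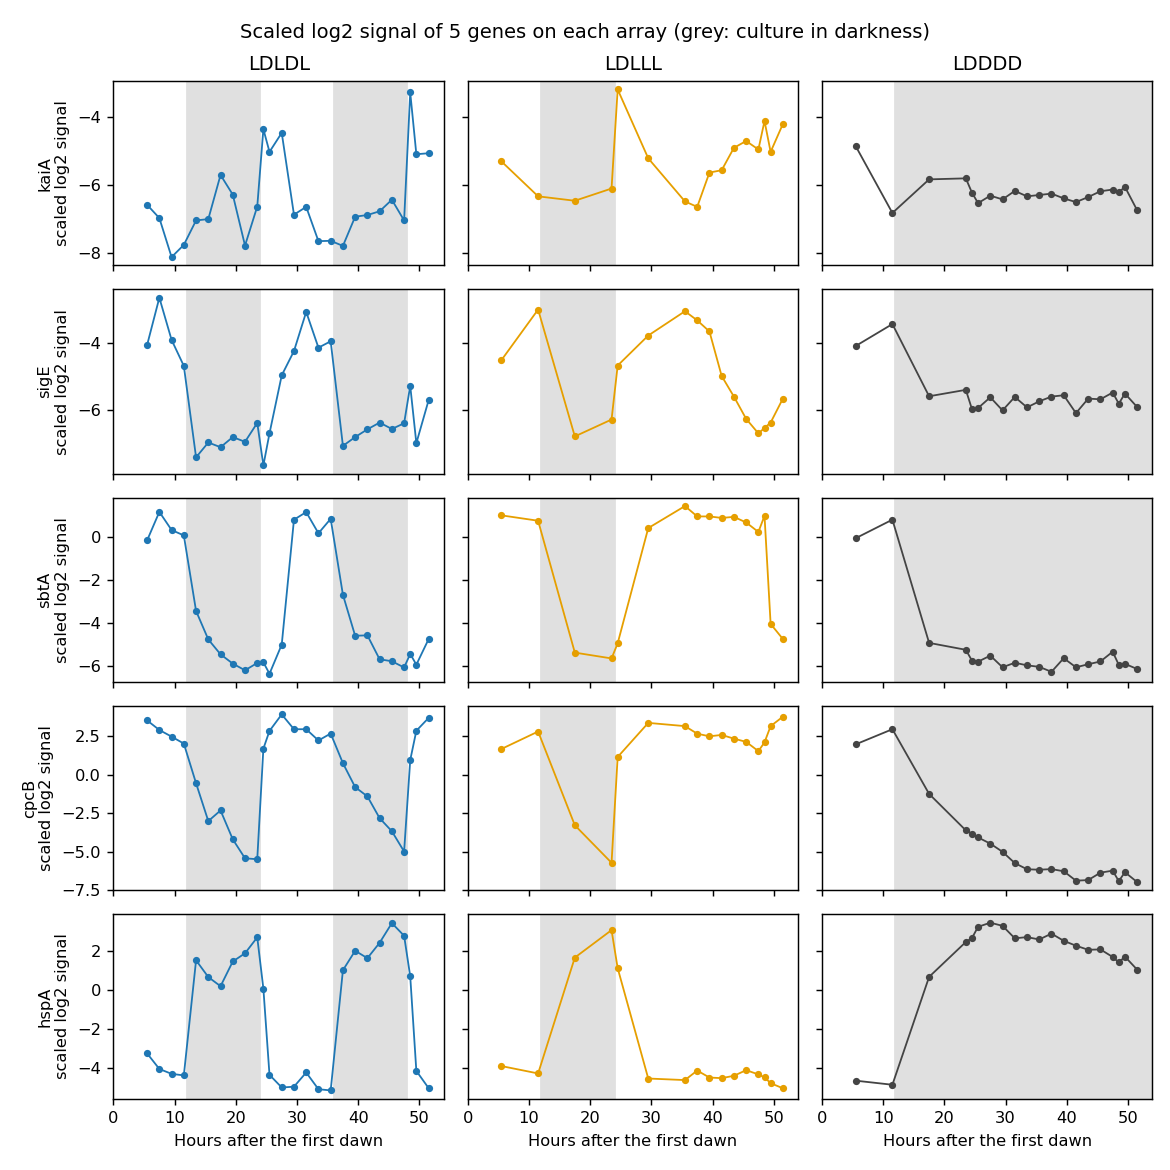
Scaled log2 signal (y axis) of kaiA, sigE, sbtA, cpcB and hspA on each array against hours after the first dawn (x axis), with 1 column per light regime, 1 point per array and grey where the light was off. In unbroken light sbtA fell between the arrays at CT0.5 and CT1.5 of day 3, from 0.98 to -4.03.

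The extra sample 30 min after dawn gives the early response to light, here CT0.5 minus CT23.5 for 3 dawns at which the light came on. Clock genes were among those that rose at once: 9 of 11 clock and output genes rose and 1 fell. kaiA rose by at least 6.31-fold, kaiC1 (slr0758) by 2.56 ± 0.47 (adjusted p = 0.000766), kaiB1 (slr0757) by 2.47 ± 0.32 (adjusted p = 0.000107) and rpaB by 2.51 ± 0.45 (adjusted p = 0.000744). The calls of 4 members, sasA (sll0750), kaiC3 (slr1942), rpaA (slr0115) and the falling cikA (slr1969), changed sign under at least 1 other setting, and the call of kaiC3 also ended without any 1 of the 3 dawns. All 35 ribosomal protein genes (median 3.35), 22 of 23 photosystem II genes (3.29), 11 of 12 photosystem I genes (3.65), all 9 ATP synthase genes (2.88) and 12 of 13 phycobilisome genes (2.81) rose. psaC stood at 7.19 ± 0.22 (adjusted p = 2.98e-07), cpcB (sll1577) of phycocyanin at 6.64 ± 0.30 (adjusted p = 6.33e-07) and rpl12 (sll1746) at 6.08 ± 0.24 (adjusted p = 3.24e-07). The signalling gene glnB (ssl0707), which encodes the nitrogen regulator PII, rose by 6.03 ± 0.41 (adjusted p = 4.22e-06), the chaperonin gene groEL1 (slr2076) by 4.31 ± 0.50 (adjusted p = 5.77e-05) and sigA by 4.21 ± 0.54 (adjusted p = 0.000101). sigH stood at -1.38 ± 0.20 (adjusted p = 0.000207), a call that ended without scaling.

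All 13 CO2 fixation genes (2.10), 16 of 17 genes of NDH-1 and the oxidases (2.00), 15 of 16 of chlorophyll and bilin synthesis (1.83) and 12 of 13 of the pili (1.33) rose. All 4 high-light-inducible genes rose (1.77), led by hliD at at least 10.68-fold, and all 4 glycogen synthesis genes rose. Inducible inorganic carbon uptake had the lowest median, -1.51, with 3 of 8 genes lower, 2 adjusted over the list alone, among them cmpA (slr0040) at -1.12 ± 0.30 (adjusted p = 0.00765). The call of cmpA ended without scaling, with the authors' matrix, with slide as a block and without the first dawn. Camera called these lists apart from the clock, glycogen synthesis and the high-light-inducible proteins, with adjusted p = 0.591 for each of the 10 with an estimated correlation. Outside the lists, slr1957 at 6.57 ± 0.32 and NC-361 at 5.95 ± 0.29 rose and slr0967 at -3.20 ± 0.19 and slr0272 at -2.87 ± 0.19 fell.

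At lights-on 6192 features changed, 4903 higher and 1289 lower, with a median over all features of 1.11. The share higher, 79.2%, ran from 41.5% under the 75th percentile over all probes to 98.5% without scaling. At the 3 dawns without a change of light limma called 0 features, with 182 at an unadjusted p under 0.05, and kaiA had 0.11 ± 0.33 (adjusted p = 1). These are 2 LDDDD dawns in darkness and 1 LDLLL dawn in light, so the mean mixes both. At the lit dawn the scaled signal of kaiA went from -4.96 to -4.12 and that of kaiC1 from -6.8 to -5.06. At the dark dawns kaiA went from -5.81 to -6.23 and from -6.14 to -6.22. There kaiC1 went from -5.67 to -6.76 and from -6.11 to -6.65. Each value is 1 array, and no dawn was tested alone. Simulated changes of log2 2 were recovered for 71.2% of features in that comparison and changes of log2 1 for 7.5%. Fitted as the difference between both kinds of dawn, 5423 features changed. Slide changes are unequal between the kinds. The first LDLDL dawn (slides 2 and 4) and the LDLLL lights-on dawn (8 and 9) cross slides. Of the dawns without a change of light only the first LDDDD dawn does (12 and 13). At the second LDLDL dawn, within slide 7, the mean signal of the ribosomal protein list went from -5.81 to -1.3.

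Lights-off was followed over the first 90 min of darkness, CT13.5 minus CT11.5 at 2 LDLDL dusks. Inorganic carbon uptake genes fell furthest: all 8 fell, with a median of -3.02. ndhD3 stood at -5.57 ± 0.54 (adjusted p = 0.00033), cmpB (slr0041) lower by at least 10.67-fold and sbtA at -3.50 ± 0.33 (adjusted p = 0.0003). ATP synthase (8 of 9 genes; -2.64), photosystem I (9 of 12; -2.18), CO2 fixation (9 of 13; -2.10), ribosomal proteins (24 of 35; -1.85), NDH-1 and oxidases (13 of 17; -1.66), phycobilisome (11 of 13; -1.65) and photosystem II (19 of 23; -1.49) fell. atpG (sll1323) stood at -3.63 ± 0.30 (adjusted p = 0.000253) and rpoC2 (sll1789) of RNA polymerase at -3.56 ± 0.32 (adjusted p = 0.000274). hspA rose by 6.04 ± 0.24 (adjusted p = 5e-06) and sigH by 1.32 ± 0.25 (adjusted p = 0.00842), and sigE stood at -2.90 ± 0.56 (adjusted p = 0.00923). Without dusk 2 the calls of sigH and sigE ended, and without scaling that of sigH ended. The clock genes kaiC1 with 0.08 ± 0.57 (adjusted p = 0.947) and kaiB1 with -0.07 ± 0.40 (adjusted p = 0.927) did not pass. Outside the lists, sll0846 rose by 3.18 ± 0.29 and NC-792 by 2.63 ± 0.20, and sll1735 at -4.31 ± 0.26 and NC-1188 at -4.86 ± 0.74 fell, the last of these without a call when dusk 2 was left out.

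Adjusted over the list alone, 9 ATP synthase, 26 ribosomal, 16 NDH-1 and oxidase, 13 phycobilisome and 21 photosystem II genes fell. Camera called 12 lists at dusk. With an estimated correlation it gave adjusted p = 0.312 for NDH-1 and the oxidases, adjusted p = 0.259 for CO2 fixation, and adjusted p = 0.208 for inorganic carbon uptake, ATP synthase, both photosystems, phycobilisome and ribosomal proteins. The hydrogenase (4 of 5 lower, 5 over the list alone; -0.71), glycogen breakdown (4 of 11 lower, 9 over the list alone; -0.59) and pili (5 of 13 lower, 9 over the list alone; -0.76) had adjusted p = 0.265, adjusted p = 0.473 and adjusted p = 0.496 with an estimated correlation. The chaperones, called upward with 1 gene higher, had a median of 0.15 that turned to -0.93 without dusk 1, and adjusted p = 0.496 with an estimated correlation.

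At dusk 1182 features changed, 70 higher and 1112 lower, with a median over all features of -0.41. The share higher, 5.9%, reached 37.3% under the 75th percentile over all probes. The count was 1727 without dusk 1 and 232 without dusk 2, 652 with normexp background correction, 3799 without scaling and 2382 with slide as a block. At 2 dusks without a change of light limma called 0 features, with 51 at an unadjusted p under 0.05. Each of these lies within a slide, while the arrays of lights-off dusk 1 lie on slides 2 and 1.

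Light in the hours that would have been dark was compared with darkness at matched CT, 6 LDLLL subjective night arrays against 12 LDLDL night arrays. Photosynthesis and carbon genes kept high levels in the light. All 12 photosystem I genes (3.94), all 8 inorganic carbon uptake genes (3.78), all 13 phycobilisome genes (3.07), all 9 ATP synthase genes (2.95), all 13 CO2 fixation genes (2.89) and 22 of 23 photosystem II genes (2.66) were higher. ndhD3 was higher by 6.08 ± 0.33 (adjusted p = 2.83e-09), sbtA by 5.83 ± 0.29 (adjusted p = 1.6e-09), psaC by 6.10 ± 0.43 (adjusted p = 3.18e-08) and the nitrate transporter gene nrtA (sll1450) by 4.27 ± 0.43 (adjusted p = 7.98e-07). hspA stood at -6.15 ± 0.32 (adjusted p = 2.41e-09). Ribosomal proteins (34 of 35, 35 over the list alone; 1.81), RNA polymerase (5 of 5; 2.12), NDH-1 and oxidases (17 of 17; 1.66), chlorophyll and bilin synthesis (15 of 16 with 1 lower; 1.28) and pili (11 of 13, 12 over the list alone; 1.03) were higher too. Among sigma factors sigA was higher by 2.46 ± 0.45 (adjusted p = 0.000198) and sigE by 1.68 ± 0.41 (adjusted p = 0.00186), and sigH lower at -1.10 ± 0.20 (adjusted p = 0.000149). The call of sigE ended with normexp correction, under quantile normalization, under the 75th percentile over all probes and after subtraction of the difference before the transfer, and that of sigH ended without scaling and with the authors' matrix. rpaB was higher by 1.79 ± 0.34 (adjusted p = 0.000231), and kaiA by 1.46 ± 0.27 (adjusted p = 0.000226), a difference that turned negative with normexp correction and passed neither under quantile normalization nor after that subtraction. Outside the lists, slr1513 at 5.85 ± 0.35 and NC-445 at 5.49 ± 0.49 were higher and slr0088 at -3.30 ± 0.35 and NC-792 at -3.24 ± 0.26 lower.

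In this comparison 5603 features differed, 4814 higher and 789 lower in the light, with a median over all features of 0.85. The share higher, 85.9%, ran from 45.7% under quantile normalization to 97.9% without scaling, and was 73.6% after the difference before the transfer was subtracted. Camera called the lists above except RNA polymerase. With an estimated correlation it gave adjusted p = 0.457 for pili and for chlorophyll and bilin synthesis, adjusted p = 0.271 for photosystem II and adjusted p = 0.258 for the other 7.

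For the time of day without a change of light, 12 LDLLL arrays from CT0.5 of day 2 were used, 6 of day and 6 of night hours. The first was taken 30 min after the last lights-on, so its response to light is part of this set. A 24 h rhythm was called for 3 of 11 genes of glycogen breakdown (7 over the list alone; mean peak 12.7 h), 3 of 17 of NDH-1 and oxidases (11.6 h) and 1 of 9 sigma factors, near the time of the former dusk. The amplitude was 3.43 with a peak at 10.85 h (adjusted p = 0.00526) for sigE, 2.09 with a peak at 12.00 h (adjusted p = 0.000412) for the glycolytic gene gap1 (slr0884). It was 1.65 with a peak at 13.74 h (adjusted p = 0.00388) for the transaldolase gene tal (slr1793), 1.30 with a peak at 12.32 h (adjusted p = 0.00522) for pfkB1 (sll1196), and 2.16 with a peak at 11.27 h (adjusted p = 0.000229) for ctaC1 (slr1136) of cytochrome oxidase. Amplitudes of genes that peaked near the former dawn were 2.18 with a peak at 0.28 h (adjusted p = 0.0254) for kaiA and 1.36 with a peak at 2.35 h (adjusted p = 0.0284) for the glycogen synthesis gene glgC (slr1176). The call of pfkB1 ended without scaling and that of glgC with slide as a block. The clock genes kaiC1, at 2.21 with a peak at 1.05 h (adjusted p = 0.0823), and kaiB1, at 2.01 with a peak at 0.98 h (adjusted p = 0.092), did not pass over all features, but both did without scaling, under the 75th percentile over all probes, with a linear trend as a covariate and without the array 30 min after lights-on. Adjusted over the list alone, 12 of 13 phycobilisome, 9 of 9 ATP synthase, 8 of 8 inorganic carbon uptake and 5 of 11 clock genes passed this fit, against 0, 1, 0 and 1 over all features. The carbon uptake genes were low 30 min after lights-on and at CT1.5 and CT3.5 of day 3. Their fit cannot tell a rhythm from events at these times.

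In all 222 features, 80 of them coding, had a rhythm in unbroken light, with 1766 at an unadjusted p under 0.05. The 12 arrays span 27 h, so a recurring pattern cannot be told from a trend or a single event. The count was 644 with a linear trend as a covariate, 386 with normexp correction, 1173 under quantile normalization, 911 with the authors' matrix, 875 under the 75th percentile over all probes, 143 with no filter and 75 with slide as a block. Without the array 30 min after lights-on 917 features had a rhythm, among them all of the 222. The fit recovered 39.4% of simulated rhythms with a log2 amplitude of 2 and 0% of those with 1. In the data atpC (sll1327) was called at 0.76, so these rates do not bound what the fit calls.

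Day minus night hours in unbroken light gave 0 features with limma, 922 at an unadjusted p under 0.05. Camera called 7 lists and fry 0 of 20. Inorganic carbon uptake had the lowest median, -2.48, camera adjusted p = 6.24e-09 and adjusted p = 0.69 with an estimated correlation. Higher by day were ribosomal proteins (0.45), chlorophyll and bilin synthesis (0.41), phycobilisome (0.41), ATP synthase (0.35), photosystem II (0.24) and glycogen synthesis (0.24), with adjusted p = 0.755 for phycobilisome and adjusted p = 0.69 for the others with an estimated correlation. Of its 8 genes 6 were lower by day adjusted over the list alone. Its mean signal was low on 3 of the 6 day arrays, at -6.14 30 min after lights-on and at -6.65 and -6.88 at CT1.5 and CT3.5 of day 3, against -3.33, -1.40 and -1.36 on the others. The list median was -2.01 without the array 30 min after lights-on. Simulated changes of log2 1 were recovered for 50.7% of features. The day-night difference itself differed between LDLLL and LDLDL for 3725 features, 568 higher and 3157 lower, with a median over all features of -0.40. Photosystem I (10 of 12 genes, 11 over the list alone; -4.29), photosystem II (22 of 23; -2.73) and ribosomal proteins (33 of 35, 34 over the list alone; -1.98) had a smaller difference in LDLLL. Inorganic carbon uptake (8 of 8; -3.91) had a median of 1.29 in LDLDL and of -2.48 in LDLLL. Camera with an estimated correlation gave adjusted p = 0.244 for both photosystems, adjusted p = 0.289 for ribosomal proteins and adjusted p = 0.517 for carbon uptake. psaC had -6.07 ± 0.64 (adjusted p = 3.71e-11) and hspA 6.22 ± 0.91 (adjusted p = 1.31e-07). The share higher, 15.2%, ran from 1.3% without scaling to 63.0% under the 75th percentile over all probes.

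**Figure D2:**
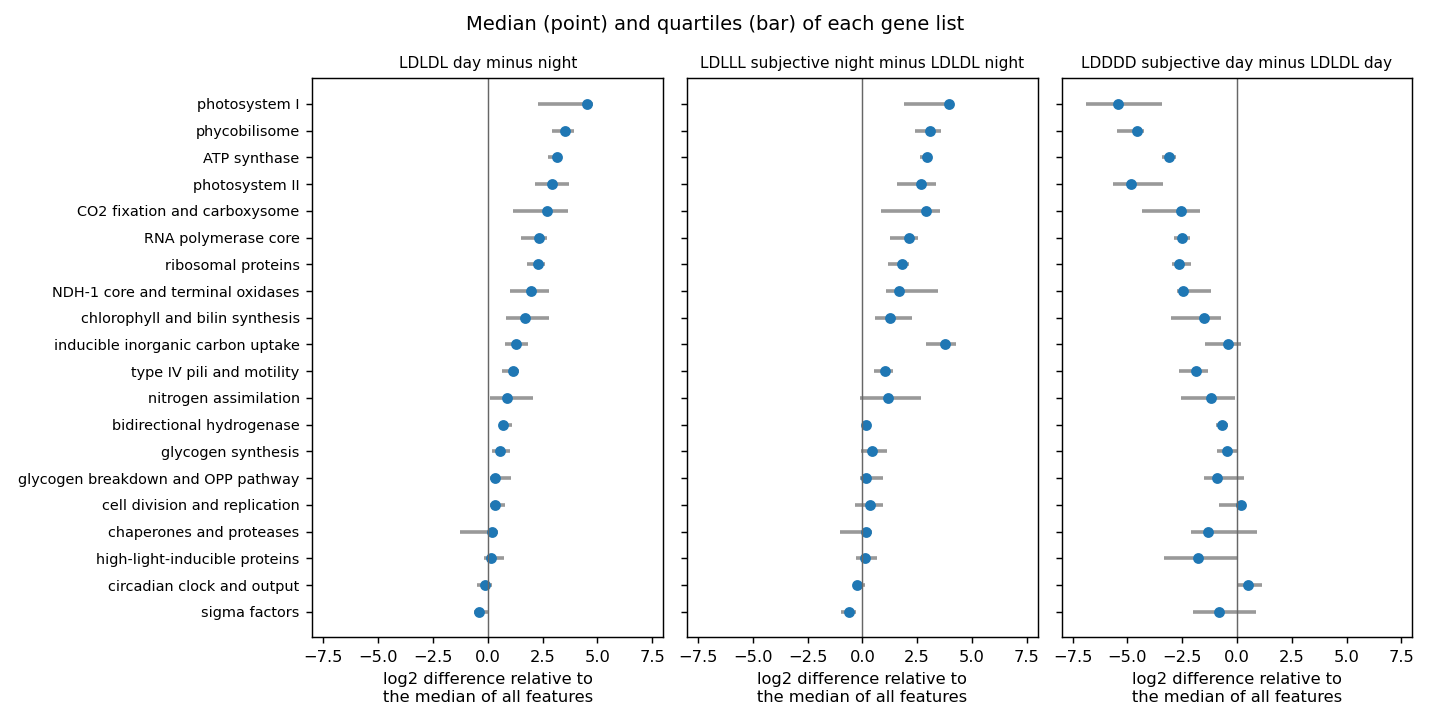
Median (point) and quartiles (bar) of the log2 difference of each gene list relative to the median of all features (x axis), for LDLDL day minus night, LDLLL subjective night minus LDLDL night and LDDDD subjective day minus LDLDL day. Photosystem I lies at 4.52, 3.94 and -5.43.

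Darkness in the hours that would have been lit was compared with light at matched CT, 10 LDDDD subjective day arrays against 14 LDLDL day arrays. The photosynthetic apparatus was lower throughout. All 12 photosystem I genes (-5.43), all 23 photosystem II genes (-4.85), all 13 phycobilisome genes (-4.57) and all 9 ATP synthase genes (-3.09) were lower. cpcB had -8.25 ± 0.37 (adjusted p = 2.39e-14), psaC -8.17 ± 0.18 (adjusted p = 2.26e-18), psbK (sml0005) -6.59 ± 0.17 (adjusted p = 8.66e-18) and psaE (ssr2831) was lower by at least 135.49-fold. All 35 ribosomal protein genes (-2.63), all 13 CO2 fixation genes (-2.54), and all 5 RNA polymerase genes (-2.53) were lower. So were 16 of 17 genes of NDH-1 and oxidases (-2.47), all 13 pili genes (-1.89) and 13 of 16 genes of chlorophyll and bilin synthesis, with 1 higher (-1.50). hspA was higher by 6.17 ± 0.54 (adjusted p = 9.87e-10), while groEL1 was lower at -3.10 ± 0.31 (adjusted p = 9.59e-09).

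Sigma factor genes were lower for 5 of 9 and higher for 2, with sigA at -3.12 ± 0.27 (adjusted p = 8.49e-10), sigF at -2.62 ± 0.26 (adjusted p = 7.89e-09), sigG (slr1545) at -2.40 ± 0.34 (adjusted p = 1.6e-06) and sigI at 1.56 ± 0.15 (adjusted p = 6.22e-09), a call that ended without scaling. Of the clock list 3 genes were higher and 2 lower, rpaB with -2.07 ± 0.15 (adjusted p = 4.92e-11) and kaiC3 with 1.21 ± 0.27 (adjusted p = 0.000363). The difference of kaiC3 turned negative without scaling, and its call ended after subtraction of the difference before the transfer. The pilin gene pilA1 (sll1694) had -3.44 ± 0.33 (adjusted p = 3.69e-09) and the replication initiator gene dnaA 1.45 ± 0.13 (adjusted p = 1.19e-09), a call that ended without scaling. Outside the lists, slr0272 at 2.61 ± 0.19 and NC-792 at 3.46 ± 0.20 were higher and ssl0020 at -6.93 ± 0.22 and NC-14_pSYSA at -8.28 ± 0.23 lower. Camera called 10 lists, among them the photosynthesis and ribosomal lists. With an estimated correlation it gave adjusted p = 0.553 for photosystem I, photosystem II, phycobilisome, CO2 fixation, NDH-1 and oxidases and pili. It gave adjusted p = 0.558 for ATP synthase, RNA polymerase and ribosomal proteins and adjusted p = 0.693 for chlorophyll and bilin synthesis.

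In all 6624 features differed, 2548 higher and 4076 lower in darkness, with a median over all features of -0.40. Of the 2548 features 524 were well above background on only a minority of the LDDDD arrays. Of the 4076 features 20 were so on only a minority of the LDLDL arrays. The share higher, 38.5%, ran from 6.8% without scaling to 66.8% with normexp correction, and was 23.9% after the difference before the transfer was subtracted.

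The prolonged night of LDDDD, a night that follows a dark day, was compared with the LDLDL night at matched CT, 6 arrays against 12. Sigma factor genes differed, with 5 of 9 lower and 2 higher (-1.68). sigG at -3.08 ± 0.25 (adjusted p = 2.07e-07), sigF at -2.33 ± 0.19 (adjusted p = 2.19e-07), sigB (sll0306) at -1.63 ± 0.26 (adjusted p = 0.000148) and sigH at -1.63 ± 0.21 (adjusted p = 2.38e-05) were lower, the last 2 without a call with the authors' matrix, and sigE at 1.10 ± 0.17 (adjusted p = 0.000107) was higher. Photosystem I had 9 of 12 genes lower and 1 higher (10 lower over the list alone; -2.30), phycobilisome 9 of 13 lower and 2 higher (-2.11) and photosystem II 15 of 23 lower (-1.66). psbD2 (slr0927) stood at -3.99 ± 0.20 (adjusted p = 7.38e-09) and cpcB at -3.62 ± 0.58 (adjusted p = 0.00018). The chaperonin genes groES (slr2075) at -3.11 ± 0.44 (adjusted p = 6.01e-05) and groEL1 at -2.60 ± 0.35 (adjusted p = 3.63e-05) and pilA1 at -3.32 ± 0.33 (adjusted p = 2.09e-06) were lower as well. So were glnB at -2.57 ± 0.34 (adjusted p = 2.93e-05) and nblA1 (ssl0452), which takes part in phycobilisome breakdown, at -1.99 ± 0.26 (adjusted p = 2.6e-05). Of 11 clock genes 6 were higher, kaiC3 by 1.49 ± 0.23 (adjusted p = 0.000111) and kaiB1 by 1.13 ± 0.18 (adjusted p = 0.000217). Both were also higher in LDDDD before the transfer, by 0.69 ± 0.19 and 1.13 ± 0.20, and so was sigE, by 0.79 ± 0.23. With these differences subtracted, kaiB1 turned to -0.03 and the calls of kaiC3 and sigE ended.

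Camera called 5 lists in the prolonged night. With an estimated correlation it gave adjusted p = 0.672 for both photosystems and phycobilisome, adjusted p = 0.412 for sigma factors and adjusted p = 0.673 for chaperones (4 of 11 lower; -0.85). In all 3890 features differed, 2572 higher and 1318 lower, with a median over all features of 0.36. Of the 2572 features 405 were well above background on only a minority of the LDDDD arrays. Of the 1318 features 26 were so on only a minority of the LDLDL arrays. The share higher, 66.1%, ran from 22.8% without scaling to 81.5% with normexp correction. After the difference before the transfer was subtracted, 1322 features differed and 18.5% of them were higher. The count was 2250 without scaling, 1903 with the authors' matrix and 2404 with slide as a block. Outside the lists, sll0175 at 1.70 ± 0.17 and NC-184 at 2.85 ± 0.26 were higher and ssr2848 at -5.63 ± 0.50 and NC-142 at -4.98 ± 0.27 lower.

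In unbroken darkness the time of day left little trace in the genes of the lists in the main fits, while some other fits called many more features. Of 18 arrays 10 fell in day hours and 8 in night hours, and limma called 0 features between them, with 467 at an unadjusted p under 0.05. Simulated changes of log2 1 were recovered for 71.6% of features. The simulation has no background floor, so for features near background on these arrays it may overstate what could be seen. A 24 h rhythm was called for 10 features, none of them coding, with 414 coding features and 1453 in all at an unadjusted p under 0.05. kaiA had an amplitude of 0.22 with a peak at 19.99 h (adjusted p = 0.865), kaiC1 0.06 with a peak at 0.64 h (adjusted p = 1) and sigE 0.15 with a peak at 19.28 h (adjusted p = 0.991). The last 2 of these were called with normexp correction. Detection limits these amplitudes. At the 3 dawns without a change of light, 1 of them lit, kaiA was well above background on 1 array before and 1 after. For kaiC1 it was 1 array before and 3 after, and for sigE 2 and 3. The count of 10 rhythmic features was 1769 with a linear trend as a covariate, 258 for the 16 arrays from CT0.5 of day 2, 2228 with normexp correction, 615 with the authors' matrix and 6 under quantile normalization. It was 0 without scaling, with no filter, under the 75th percentile over all probes and with slide as a block. The fit recovered 75.8% of simulated rhythms with a log2 amplitude of 2.

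The day-night difference differed between LDDDD and LDLDL for 4966 features, 945 higher and 4021 lower, with a median over all features of -0.64. All 12 photosystem I genes (-4.54) and all 35 ribosomal protein genes (-2.16) had a smaller difference in LDDDD, with adjusted p = 0.28 for both in camera with an estimated correlation. psaC had -6.65 ± 0.56 (adjusted p = 1.01e-14), rps9 -3.77 ± 0.29 (adjusted p = 4.81e-16) and hspA 6.01 ± 0.80 (adjusted p = 5.73e-09). The share higher, 19%, ran from 1.4% without scaling to 57.9% under quantile normalization.

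**Figure D3:**
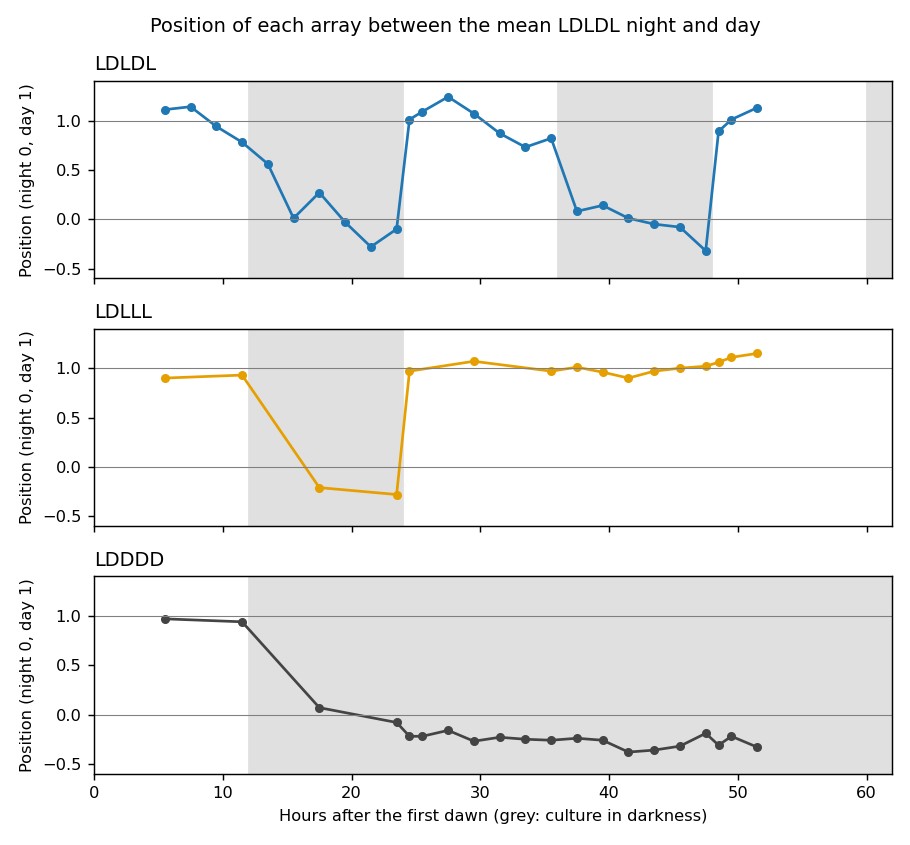
Position of each array (y axis) between the mean LDLDL night, set to 0, and the mean LDLDL day, set to 1, against hours after the first dawn (x axis), with 1 panel per regime, 1 point per array and grey where the light was off. The 6 arrays of the LDLLL subjective night lie between 0.90 and 1.02 and the 10 of the LDDDD subjective day between -0.33 and -0.16.

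Over all features each array can be placed between the LDLDL night (0) and day (1). The LDLLL subjective night lay at 0.98 ± 0.05 (SD, n = 6), the lit morning after it at 1.11 ± 0.04 (n = 3), the LDDDD subjective day at -0.25 ± 0.05 (n = 10) and the prolonged night at -0.29 ± 0.07 (n = 6). Before the transfer the 5 lit LDLLL arrays lay at 0.97 ± 0.07 and the 2 LDDDD day arrays at 0.95 ± 0.02. The night arrays before the transfer lay at -0.24 ± 0.05 (LDLLL, n = 2) and -0.01 ± 0.10 (LDDDD, n = 2) and the 12 LDLDL night arrays from -0.32 to 0.56, so a night in a light-dark regime reached the position of the subjective day in darkness.

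Arrays taken before the regimes parted measure what separates the regimes or the array runs otherwise. Clock and output genes were higher in both other regimes than in LDLDL, 7 of 11 in LDLLL (0.56), with cikA at 1.10 ± 0.17 (adjusted p = 0.000411) and kaiB1 at 1.00 ± 0.19 (adjusted p = 0.00119). In LDDDD 9 of 11 were higher (0.66), with cikA at 1.42 ± 0.25 (adjusted p = 0.00363) and kaiC1 at 1.20 ± 0.28 (adjusted p = 0.00934). NDH-1 and oxidase genes were higher in LDDDD for 14 of 17 (0.39), with ndhG (sll0521) at 1.21 ± 0.17 (adjusted p = 0.00293). Under quantile normalization the calls of all genes named here ended, and in LDDDD they ended without scaling and with slide as a block too, as did that of cikA in LDLLL with normexp correction and with the authors' matrix. Camera called 4 lists in LDLLL, the clock, phycobilisome (-0.33), photosystem II (-0.31) and photosystem I (-0.30), with adjusted p = 0.879 for each with an estimated correlation. Of the last 3 lists no gene was called lower, and the medians of both photosystems turned to 0.06 and 0.03 with the authors' matrix. In LDDDD it called the clock, NDH-1 and chaperones and proteases (1 of 11 lower; -0.45), with adjusted p = 0.82 for each. Detection limits these values, since cikA in LDDDD was well above background on 2 of 4 arrays, against 4 of 8 in LDLDL, kaiC1 on 2 of 4 and 2 of 8 and ndhG on 2 of 4 and 7 of 8. kaiC2 (sll1595), counted among the 9, was on 0 of 4 and 0 of 8. In LDLLL kaiB1 was so on 7 of 7, against 3 of 10, and cikA on 7 of 7 and 5 of 10. For LDLLL 7 arrays against 10 gave 2561 features, 2502 higher and 59 lower, with a median over all features of 0.32. For LDDDD 4 arrays against 8 gave 2684 features, 2583 higher and 101 lower, with a median of 0.41. Of these 2583 features 683 were well above background on fewer than 2 of the 4 LDDDD arrays.

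These counts depend on the processing. For LDLLL they were 881 with normexp correction, 89 under quantile normalization (71.9% higher against 97.7%), 1484 without scaling, 655 with the authors' matrix, 1382 under the 75th percentile over all probes and 810 with slide as a block. For LDDDD they were 4339, 124 (60.5% higher against 96.2%) and 0 in the first 3 of these and 0 with slide as a block. They were 1414 and 1101 without the first and second night array before the transfer. Regime and slide coincide, with no slide holding arrays of more than 1 regime, so outside these arrays regime and array run cannot be separated.

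The series covers noncoding features as well. Antisense and NC features together had a 24 h rhythm in LDLDL for 1313 of 2140 (61.4%), against 2336 of 3323 coding features (70.3%), an odds ratio of 0.67 (Fisher's exact test, two-sided, adjusted p = 2.52e-11 over 5 comparisons). The share was 57.4% for antisense features alone (odds ratio 0.57, adjusted p = 3.67e-18), and NC features had 73.3% (adjusted p = 0.206), features inside genes 69.2% (adjusted p = 0.424) and 5'UTR features 77.4% (adjusted p = 0.000313). Features are not independent of each other. The odds ratio for antisense and NC features was 1.07 with slide as a block and 1.08 without the 4 LDLDL night arrays of slide 6. Across 1609 pairs of an antisense feature and its sense gene the median Spearman rho over the 26 arrays was 0.07, against 0.10 with the antisense features shuffled over the genes.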

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

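Tests of the patterns below were chosen after the result was seen, apart from the background test of the first pattern, the comparisons of day-night differences, Dixon's test and the counts of other splits, which were planned.

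Photosystem I and II, phycobilisome, ATP synthase and ribosomal protein genes were lower in the LDDDD subjective day than in the LDLDL day. Scaling is argued against as the source. Under 5 scalings the highest of the 5 list medians, here not relative to all features, was -1.39. An offset common to all LDDDD arrays is argued against too, since before the transfer the lowest of the 5 was 0.09, and -0.32 relative to all features. The arrays before the transfer lie on slide 12 and share no slide or scan day with the subjective day arrays. They cannot speak to an offset of the later slides alone. Signal lost in the background is argued against by the 51 of 92 members well above background on every array of both groups, whose median was -3.22. For an offset of slides 14 and 16, the 6 subjective day and 2 prolonged night arrays there were compared. For 41 of the members the difference from LDLDL was higher in the prolonged night by at least 1.33 per list and scaling. That cannot decide, since a level in darkness that did not follow the time of day would give such a gap with an offset too. Slide 13 holds the other 4 subjective day arrays. Its offset alone is argued against as the whole source, since without those arrays the highest of the 5 medians was -1.32. Offsets of these slides, as part or together as the whole of the fall, stay open. Loss of light may be the source, a hypothesis found and tested on the same data.

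In unbroken light the inducible inorganic carbon uptake genes fell between CT0.5 and CT1.5 of day 3, with no change of light in the design. A difference between slides is argued against, because both arrays lie on 1 slide and the list mean fell by 5.29 between them, and so is scaling, with a smallest fall of -3.93 under 5 scalings. A rhythm of the list with the time of day cannot be told apart from an event of that morning, because only 1 morning was sampled in unbroken light and the LDLDL mornings follow a dark night. Handling between these samples is not recorded and stays open, and no biological explanation was tested.

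Antisense and NC features together were rhythmic less often than coding features in LDLDL, which held for antisense features (57.4% against 70.3%) and not for NC features (73.3%, adjusted p = 0.206). Dim features are argued against as the whole source, with an odds ratio of 0.80 among features well above background on at least 13 of the 26 arrays. The 4 night arrays of slide 6 may carry the difference, since without them the odds ratio was 1.08 (Fisher's exact test, p = 0.213), and with slide as a block it was 1.07. No biological explanation was tested.

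The day-night difference was tested between regimes and differed for 3725 features between LDLLL and LDLDL and for 4966 between LDDDD and LDLDL. The change at lights-on dawns differed from that at dawns without a change of light for 5423 features, 4393 higher and 1030 lower. The change at lights-off dusks differed from that at dusks without a change of light for 226 features, 11 higher and 215 lower, with 1411 at an unadjusted p under 0.05. Slide changes are unequal between the kinds of dawn and of dusk, as given above.

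Among the 5 lit LDLLL arrays before the light stayed on, replicate 1 (CT5.5 of day 1) stood apart with 73.9% of spots well above background, against 83.8% for the next and 84.8% for the highest. In the same group replicate 5 (CT11.5 of day 2) had a 75th percentile of 19963, against 30072 for the next and 31667 for the highest. Dixon's test at the 5% level was run on 12 sets, of which 0.6 would stand apart by chance, and 2 did.

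Other splits of the same arrays into groups of the same sizes were counted, 100 per comparison with the real one included. No other split gave as many features for LDLDL day against night (5579 features; highest other split 3012), the LDLDL rhythm (5562; 2982), the LDLLL subjective night (5603; 2373), the LDDDD subjective day (6624; 2964), the LDDDD prolonged night (3890; 2722), the day-night differences of LDLLL (3725; 22) and LDDDD (4966; 1956) against LDLDL, LDLLL before the transfer (2561; 154), LDDDD before the transfer (2684; 1571) and the rhythm in unbroken light (222; 1). This argues against a chance split of exchangeable arrays. Between regimes the labels were shuffled over all arrays and not within circadian time, so the other splits were less balanced in time than the real one. For the rhythm in unbroken darkness 2 of the 100 orders of the arrays, the real one among them, gave as many features (10; highest other 22). That share lies under 0.05, but another order called more features than the real one, so chance is not called excluded. All these splits and orders take arrays as exchangeable, while neighbours in time share slides. With slide as a block the rhythm gave 75 features in unbroken light and 0 in darkness. LDDDD before the transfer, with its arrays on 1 slide, gave 0 as well. Slide is therefore not excluded as a source. Day against night hours in unbroken light (0; 569) and darkness (0; 1475) gave no more than any of the 100 splits. What the splits that call so many have in common was not tested. For the dawns with lights-on (6192; 0) and without a change of light (0; 0) there are 4 patterns of signs each, too few for a share under 0.05.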

How the results depend on the processing

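Alternatives are named with the processing, and those chosen after seeing the data include all for the noncoding share. Of the values for comparisons, 149 kept their count within 1.5 times, or for noncoding rhythms an odds ratio below 1 with p under 0.05. The balance of higher and lower features was not part of this rule, and its range is given with the comparisons above. Of the values for lists and named genes, 4430 stayed within the spread of the list or kept sign and call. Of the rest 143 moved, 84 lost and 11 gained a call and 21 reversed. For comparisons the values that did not keep theirs follow, for lists and named genes only the reversals, and unless the alternative itself uses fewer arrays or features the cause was not tested.

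With normexp correction lights-off dusk gave 652 features, the rhythm in unbroken light 386 and in darkness 2228, and the comparisons before the transfer 881 (LDLLL) and 4339 (LDDDD). Under quantile normalization these rhythms gave 1173 and 6 and these comparisons 89 and 124. Without scaling dusk gave 3799, the prolonged night 2250, the rhythm in darkness 0 and the comparisons before the transfer 1484 and 0. With the authors' matrix the prolonged night gave 1903, the rhythms 911 and 615 and LDLLL before the transfer 655. With slide as a block dusk gave 2382, the prolonged night 2404, the rhythms 75 and 0 and the comparisons before the transfer 810 and 0. With the 75th percentile over all probes the rhythms gave 875 and 0 and LDLLL before the transfer 1382. With no filter the rhythms gave 143 and 0, and with a linear trend 644 and 1769. Without the array 30 min after lights-on the rhythm in unbroken light gave 917, and the 16 arrays from CT0.5 of day 2 gave 258 rhythms in darkness. Scan day as a block gave 1 feature for day against night hours in darkness. Subtraction of the difference before the transfer left 1322 features in the prolonged night. Leaving out 1 dusk gave from 232 to 1727 features, and leaving out 1 LDDDD array before the transfer from 1101 to 2306. Camera with the estimated correlation called 0 of 92 list and comparison pairs.

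The odds ratio of noncoding rhythms was 0.94 with normexp correction, 0.91 under quantile normalization, 0.92 with the authors' matrix and 0.88 with the 75th percentile over all probes, and reversed to 1.07 with slide as a block and to 1.08 without the 4 night arrays of slide 6. The chaperone median at dusk reversed to -0.09 with normexp correction, -0.02 with the authors' matrix and -0.93 with slide as a block, and without 1 dusk it ranged from -0.93 to 1.36. Before the LDLLL transfer photosystem II and I reversed to 0.06 and 0.03 with the authors' matrix. Of named genes, without scaling kaiC3 in the LDDDD subjective day reversed to -0.04 and cikA at lights-on to 0.06, and after subtraction of the difference before the transfer kaiB1 in the prolonged night to -0.03. With normexp correction kaiA in the LDLLL subjective night reversed to -0.06, sasA at lights-on to -0.24 and kaiB2 by day to 0. Under quantile normalization and the 75th percentile over all probes, in this order, sigF by day reversed to -0.15 and -0.24, and at lights-on sasA to -0.22 and -0.15, rpaA to -0.65 and -0.62 and kaiC3 to -0.84 and -0.61. kaiB3 by day reversed to -0.12 under the last of these. Signal over background limits the dark arrays, the dimmest of which had 7633 spots well above it.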

Other observations

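Tests in this part were chosen after the data were seen.

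During the 34 h of darkness sampled in LDDDD (18 arrays) several photosynthesis transcripts fell with time, which runs with the 5 slides that hold these arrays. The photosystem II reaction centre genes psbA2 (slr1311) and psbD2 fell with log2 slopes per 24 h of -2.39 ± 0.14 (adjusted p = 3.13e-10) and -3.17 ± 0.30 (adjusted p = 9.73e-08), psaA (slr1834) of photosystem I with -2.66 ± 0.19 (adjusted p = 2.33e-09), and cpcB and cpcC1 (sll1580) of the phycobilisome with -3.15 ± 0.37 (adjusted p = 2.03e-06) and -3.07 ± 0.27 (adjusted p = 4.8e-08). By list, 10 of 12 photosystem I genes (median slope -1.01 relative to that of all features), 10 of 13 phycobilisome genes, where 1 rose (-0.95), 16 of 23 photosystem II genes (-0.55), 5 of 9 sigma factor genes, where 1 rose (-0.65), and 5 of 11 chaperone and protease genes (-0.32) fell. These list medians, which the 75th percentile over all probes and no scaling leave unchanged by construction, kept their direction under the 4 other settings tried, but with the authors' matrix they shrank to -0.27, -0.31, -0.19, -0.20 and -0.07 and with normexp correction to -0.52, -0.58, -0.44, -0.28 and -0.18. Within slides they were -1.74, -1.49, -1.01, -0.05 and -0.25, which leaves the sigma factors near 0. sigG fell with -2.38 ± 0.23 (adjusted p = 1.28e-07) and pilA1 with -2.42 ± 0.23 (adjusted p = 1.6e-07), while kaiC3 with 0.42 ± 0.13 (adjusted p = 0.0161) and sigD (sll2012) with 0.40 ± 0.10 (adjusted p = 0.0047) rose. In all 910 features rose and 1258 fell, with a median slope of -0.13. The balance depends on the scaling, with 1939 rising and 1175 falling under quantile normalization (median 0.09), 1222 and 1162 under the 75th percentile over all probes and 738 and 1279 with normexp correction. With slide as a random block 320 rose and 877 fell. Within slides 2 rose and 62 fell, and of the genes named here psaA at -2.64 ± 0.46 (adjusted p = 0.0221), psbA2 at -1.57 ± 0.33 (adjusted p = 0.0316) and cpcC1 at -3.21 ± 0.69 (adjusted p = 0.0381) passed, while psbD2, cpcB, sigG, pilA1, kaiC3 and sigD did not.

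Antisense features and their sense genes showed no common direction over the LDLDL day. Of 1609 pairs 674 had both members called between day and night, 345 in the same and 329 in opposite directions, where 350 in the same direction would follow if both were independent. Pairs are not independent replicates, and no test was made of that difference.

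No array was a copy of another: 0 pairs were identical, and the closest, replicates 3 and 4 of the LDDDD prolonged night, correlated at 0.9957 across features.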
